A study of Homo sapiens with 6 samples.

How the data were processed

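Total RNA was taken from DU145 cells, an established human prostate carcinoma line, after 24 h with 5 µM OTI-611 or with DMSO. Per the labels' protocols, RNA was extracted with a miRNeasy kit, messenger RNA was reverse-transcribed and amplified by the Geo-seq method, and libraries were made with a TruePrep kit, which fragments and tags DNA by transposition. Amplified reads carry no molecular identifiers that the labels name, so read numbers are not numbers of molecules. The labels give 3 samples per group and do not say whether they came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Samples were assigned to groups by their labels.

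The submitters' processing notes name CASAVA 1.7, FastQC, TopHat2 2.0.9, Cufflinks 2.1.1, HTSeq and the genome build mm10, without the role of each. mm10 is a mouse build, whereas all 32692 gene IDs of the table are human Ensembl IDs and 0 are mouse IDs, so the build, annotation and filters the authors used for these values are not established. The deposited table has 1 column per library and no named unit, and 0 columns were left unused. The authors deposited 5 columns whose values were taken as RPKM. They have decimals, sum to between 304260 and 314127 per library, and their low values come in steps inversely proportional to gene length. FPKM, which counts fragments in place of reads, would give such steps too, and the values do not tell these units apart. If the unit is FPKM, the reads estimated here are fragments. Between 73.7% and 77.0% of low values were whole numbers of reads within 0.05, using GENCODE v29 exon lengths, and the steps give the estimated depths in the report. The column DMSO 1 is treated as a score, since the authors deposited it as whole numbers only. It lay 0.51, 0.52, 0.51 and 0.53 below the mean of DMSO 2 and DMSO 3 in genes at 1 to 2, 2 to 5, 5 to 10 and 10 to 50 RPKM, close to what dropped decimals would give, but 0.918 ± 0.098 (SE) below it at 50 to 200 RPKM, so dropped decimals are the reading used here and not all of the difference. It listed 20137 genes at 0, of which 10663 were above 0 in both other DMSO libraries. The design, set before the data were examined, named a count test in case the table held counts and limma in case it held normalized values, and the latter applied, so the count tests were not run.

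Values were analysed as log2(value + 1), for genes with a mean of at least 1 over the 6 libraries, with limma 3.58.1 in R 4.3.3 (linear model with the group as its only term, empirical Bayes with a mean-variance trend, two-sided, Benjamini-Hochberg adjustment over the genes tested, threshold 0.05). Fold changes are on the log2(value + 1) scale, which understates the change of low genes, and the lower values of DMSO 1 lower its group's mean most for low genes. Ratios named as fold are of the values themselves. The 45 gene lists were fixed before the data were examined, as were the tests and most of the other settings tried. The 37 lists with at least 5 tested genes were tested with camera at a preset inter-gene correlation of 0.01, which compares a list with the other genes, and again with an estimated correlation. That estimate and its test rest on the spread between only 6 libraries. A list that does not pass there is therefore not shown to be unchanged. The fry test, which asks whether a list's genes move on balance one way and makes no comparison with other genes, was an alternative. Members counted as higher or lower passed the threshold adjusted over all genes, and adjusting over the list alone changed the counts of 2 lists only, where the report gives both. Of the 846 list entries, older aliases included, 776 matched a gene of the table.

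The named genes follow a fixed rule: CHD1L, FOXO3 and BBC3, then the 15 highest rises and the 15 largest falls among genes past the threshold whose libraries separate the groups and whose higher group mean is at least 5, then up to 4 tested members of each list with the smallest p, and the 10 genes with the smallest p overall. Clone names, numbered open reading frames, LINC numbers, U and Y RNAs, pseudogenes and genes without a symbol were passed over in the rises and falls. List members named beyond those 4 were chosen after their values were seen. Gene types, lengths, shared exon bases and positions come from GENCODE release 29 on GRCh38, in which 30667 of the 32692 IDs were found. RPKM of copies with near-identical sequence, of genes inside others and of antisense genes are uncertain.

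Replicates were compared before averaging. In reads estimated from the steps, the median squared difference between libraries of one group was 3.24 times the counting expectation for DMSO 2 and DMSO 3 and 4.28 to 5.23 times for the OTI-611 libraries, so none of the libraries compared looked like 1 library deposited 2 times, and 61.3 to 72.0 times between groups. DMSO 1, which gave no depth estimate, was not compared in this way. The fit was tested on simulated data for 11822 genes of this comparison, with 200 genes changed and the decimals of DMSO 1 dropped. It recovered 38.8% of genes changed by 0.25 on the log2 scale, 66.0% at 0.5 and 100% at 1 and at 2, and called 0.077% of unchanged genes. In the data 7805 of 11978 genes passed, and the adjustment is less strict where more genes change. The simulated shares therefore do not measure recovery or false calls in the data. Alternatives covered each library left out, a replicate block, other pseudocounts, filters and scalings, a robust prior, array weights and other list tests. Added after seeing the data were 0.5 added to DMSO 1, every library cut to whole numbers, and protein-coding genes only. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The gene families of the closing section, the bands of expression level and the limit of 20 RPKM for low ribosomal protein genes were set after values were seen. Bootstrap intervals used 2000 draws of genes, permutation tests 100000 permutations, and lists matched on level drew 10000 lists from the 100 genes nearest in mean to each member.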

Results

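RNA was measured in DU145, a human cell line derived from a prostate carcinoma, after 24 h with 5 µM OTI-611 or with its solvent DMSO. OTI-611 is a compound known here by its code name only. Each group held 3 libraries, numbered 1 to 3 as the labels number them. The deposited table gives 1 value for each of 32692 human genes in each library. In 5 of the 6 libraries the values behave as RPKM, reads scaled to gene length and library depth. The library DMSO 1 holds whole numbers only, read here as the same quantity with its decimals dropped. Its values lay 0.51 to 0.53 below the mean of DMSO 2 and DMSO 3 in bands from 1 to 50 RPKM, and 0.918 ± 0.098 (SE) below it in 1042 genes at 50 to 200, further than dropped decimals alone would place them. Read counts were not used here. The step between low values gave an estimated depth of 30.7 M and 32.3 M reads for DMSO 2 and DMSO 3 and of 37.3 M, 37.2 M and 37.6 M reads for the 3 OTI-611 libraries, and gave no estimate for DMSO 1. The first principal component held 82.3% of the variance and separated the groups, and the second held 8.84% and set DMSO 1 apart from the other libraries.

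The series title names CHD1L, a chromatin remodeller activated by poly(ADP-ribose), as the target, and an axis from the transcription factor FOXO3 to PUMA, the pro-apoptotic protein encoded by BBC3. FOXO3 and BBC3 both rose with OTI-611. FOXO3 (ENSG00000118689) rose from 6.52 ± 0.45 to 14.1 ± 0.45 RPKM (SD, n = 3 per group), a log2 fold change of 1.01 ± 0.055 (SE) with a limma adjusted p of 4.97e-07. BBC3 (ENSG00000105327) rose from 1.17 ± 0.19 to 4.15 ± 0.12 RPKM (SD, n = 3 per group), a log2 fold change of 1.25 ± 0.096 (SE) with a limma adjusted p of 3.70e-06. Measured against DMSO 2 and DMSO 3 alone, the OTI-611 mean was 2.08-fold higher for FOXO3 and 3.30-fold higher for BBC3, and all 3 OTI-611 libraries lay above all 3 DMSO libraries for both genes. Adjusted over the list alone, p was 3.93e-08 for FOXO3 and 3.72e-07 for BBC3. The study named these genes, so that adjustment is not independent evidence of their direction.

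CHD1L (ENSG00000131778) was listed at 0 in DMSO 1, which holds whole numbers only, at 0.662 in DMSO 2 and at 0.691 RPKM in DMSO 3. With OTI-611 it was listed at 0.585, 0.792 and 0.546 RPKM. Its mean lay under the minimum of 1 set for testing. Fitted with no filter on low values, its log2 difference was 0.21 ± 0.25 (SE, limma adjusted p = 0.64), and without DMSO 1 it was -0.03, so no difference in CHD1L was detectable at these levels. In GENCODE v29 on GRCh38, CHD1L lies on chromosome 1 from 147242641 to 147295766, FOXO3 on chromosome 6 from 108559835 to 108684774 and BBC3 on chromosome 19 from 47220822 to 47232766. Exons of other genes cover 7.85% of the exon bases of CHD1L, 2.52% of those of BBC3 and 0% of those of FOXO3. The strand and the handling of reads on shared bases are not given in the sources used here. Of the other FOXO genes, FOXO4 had 1.54 ± 0.48 RPKM with DMSO and 1.09 ± 0.14 with OTI-611 (SD, n = 3 per group), a log2 fold change of -0.26 with an adjusted p of 0.18 in limma. Without DMSO 1 its log2 fold change was -0.43 with a limma adjusted p of 0.0054. FOXO1 and FOXO6 lay under the minimum for testing.

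**Figure D1:**
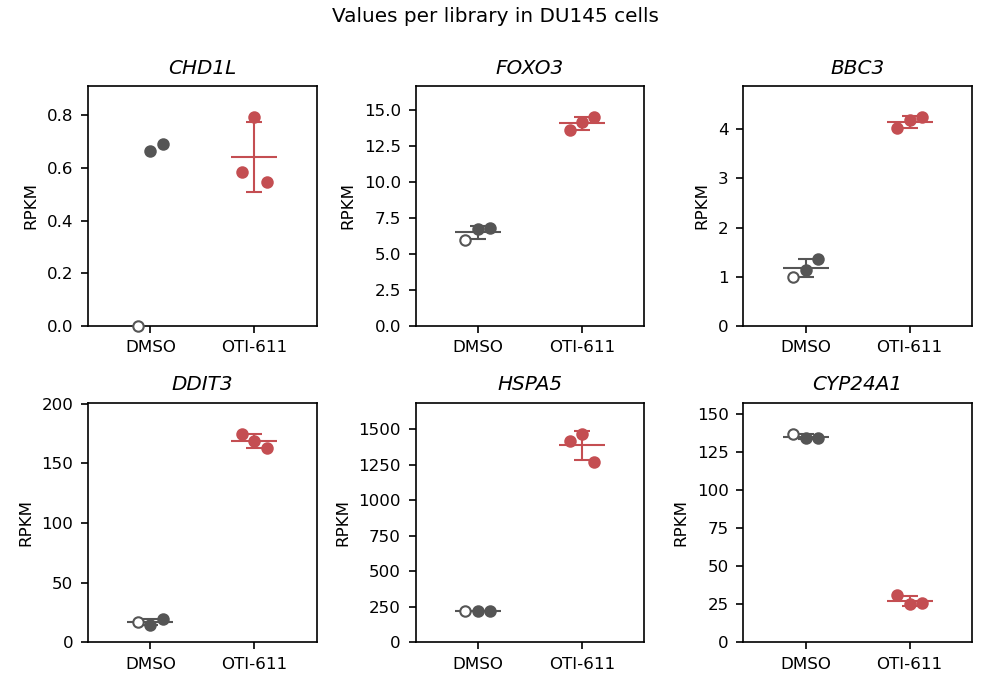
Values in RPKM (linear axes from 0) of CHD1L, FOXO3, BBC3, DDIT3, HSPA5 and CYP24A1 in the 3 DMSO libraries (grey) and the 3 OTI-611 libraries (red); each point is a library, the open point is DMSO 1, in whole numbers, and bars are the mean and SD (none is drawn for CHD1L with DMSO). FOXO3 rose from a mean of 6.52 to 14.1 and BBC3 from 1.17 to 4.15, while the CHD1L libraries with decimals overlap between 0.546 and 0.792.

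Across the transcriptome, MMP1, which encodes interstitial collagenase, had the highest rise on the log2(value + 1) scale among the genes named by the fixed rule, from 3.59 ± 0.52 to 96.4 ± 1.0 RPKM (SD, n = 3 per group; log2 fold change 4.41). DDIT3, the stress transcription factor CHOP, rose from 17.1 ± 2.4 to 169 ± 5.9 RPKM, and HSPA5, the main chaperone of the endoplasmic reticulum, from 221 ± 2.9 to 1385 ± 102 RPKM. CYP24A1, the enzyme that breaks down vitamin D hormones, had the largest fall on that scale among the named genes, from 135 ± 1.7 to 27.5 ± 3.3 RPKM (log2 fold change -2.26). Of 11978 genes tested, 7805 passed an adjusted p of 0.05 in limma, 3332 higher and 4473 lower with OTI-611. The median absolute log2 fold change of these genes was 0.39, and 229 rose and 250 fell by at least 1 on the log2 scale. In 8405 genes (70.2% of those tested) the 3 OTI-611 libraries all lay on one side of the 3 DMSO libraries, against 10% by chance. Without DMSO 1, 8263 genes passed, of which 7468 were among the 7805 and none of these changed direction. The excess of falls over rises depended on scaling. Quantile normalization gave 4085 higher and 4115 lower, and rescaling to the median log ratio gave 3986 higher and 3978 lower.

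The other 12 rises named by the rule were TRIB3 (log2 fold change 2.52), a pseudokinase induced by stress, TMEM158 (from 2.34 to 18.0 RPKM), the uridine phosphorylase UPP1 (2.43), PPP1R15A (2.19), which directs a phosphatase to the initiation factor eIF2, CTH (2.19), an enzyme of cysteine synthesis, the MAP kinase phosphatase DUSP5 (2.14), the transcription factor NFIL3 (from 21.9 to 97.0 RPKM), SLAMF7 (2.09), SLFN5 (1.91), and the short RNA genes SNORD53 (3.02), MIR616 (2.54) and SNORA72 (2.31). SNORD53, MIR616 and SNORA72 are uncertain, since a few reads on so short a gene give a high RPKM, and MIR616 lies inside DDIT3, from 57519163 to 57519259 on chromosome 12 in GENCODE v29. Other falls were MUC1 (-1.89), which encodes a mucin, TP53I3 (-1.88), S100A4 (-1.83), the CDK4 and CDK6 inhibitor CDKN2C (-1.83), ENPP2 (-1.81), which encodes autotaxin, NNMT (-1.81), VAMP1 (-1.73), the alpha tubulin TUBA1A (-1.70), LMO3 (-1.63), PTGES (-1.62), IMPA2 (-1.60) and the microRNA genes MIR4477B (-2.03) and MIR6075 (-1.70), both uncertain for the same reason. The 10 genes with the smallest p included NIBAN1 (1.64), GTPBP2 (1.84), the tRNA synthetases AARS1 (1.45) and SARS1 (1.06), MIA2 (1.69) and the autophagy gene MAP1LC3B (1.28), besides MMP1, HSPA5 and UPP1.

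**Figure D2:**
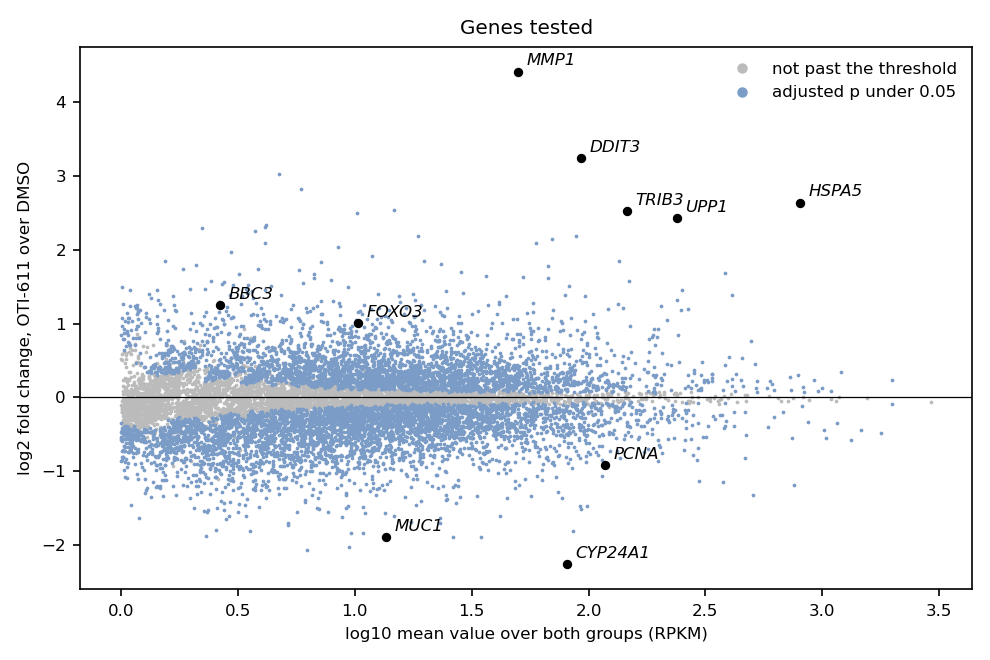
Log2 fold change (OTI-611 over DMSO, on log2(value + 1)) against the log10 mean value in RPKM for the 11978 genes tested, each point a gene; blue points passed an adjusted p of 0.05 in limma, grey points did not, and black points are labelled genes. MMP1 lies highest among the labelled genes at 4.41 and CYP24A1 lowest at -2.26.

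Genes of the stress response to misfolded protein and to amino acid shortage rose together. In the fixed list of the integrated stress response, 19 of 22 tested members rose and 3 fell, with a median log2 fold change of 0.99 (camera adjusted p = 1.32e-08). The call was lost with an estimated correlation (adjusted p = 0.49), a test that can miss real changes with only 6 libraries. TRIB3, SLC3A2, CEBPG and DDIT3 rose by 2.52, 1.68, 1.19 and 3.24 on the log2 scale, and GDF15 (2.29) and ASNS (1.84) also rose. The 3 members that fell were the cystine transporter SLC7A11 (-0.30), VLDLR (-0.29) and ATF4 (-0.17), the transcription factor that gives the response its targets. Of 20 unfolded protein response genes, 18 rose, 1 fell and 1 did not pass, with a median of 0.79 (camera adjusted p = 1.32e-08, and adjusted p = 0.49 with an estimated correlation). HSPA5 (2.64), HERPUD1 (1.78), HSP90B1 (0.93) and CALR (0.77) rose, CREB3L2 (-0.42) fell, and CRELD2 stood at 0.05.

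The lists for FOXO targets, autophagy and early response genes also rose. Of 28 FOXO target genes tested, 16 rose, 7 fell and 5 did not pass, with a median log2 fold change of 0.28 (camera adjusted p = 0.034, and adjusted p = 0.57 with an estimated correlation). MAP1LC3B (1.28), PMAIP1 (1.16), RICTOR (0.73) and GADD45A (1.27) rose, while the antioxidant enzymes CAT (-0.55), PRDX3 (-0.46) and SOD2 (-0.30) fell. Of 21 autophagy and lysosome genes, 14 rose and 4 fell, with a median of 0.25 (camera adjusted p = 0.0052, and adjusted p = 0.49 with an estimated correlation). The cathepsins CTSL (0.54) and CTSB (0.61) rose, and ATP6V0D1 (-0.43), ATG7 (-0.25), ATP6V1H (-0.14) and WIPI2 (-0.11) fell. Of 17 immediate early and AP-1 genes, 12 rose and 3 fell, with a median of 0.93 (camera adjusted p = 4.48e-04, and adjusted p = 0.57 with an estimated correlation). ETV5 (1.13), DUSP5 (2.14), PHLDA1 (1.00) and ATF3 (1.65) rose, while EGR1 (-1.23), JUNB (-1.22) and FOSL2 (-0.43), themselves early response transcription factors, fell.

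Genes for DNA replication fell. Of 31 G1/S and replication genes tested, 26 fell, 4 rose and 1 did not pass, with a median of -0.40 (camera adjusted p = 7.07e-05, and adjusted p = 0.49 with an estimated correlation). PCNA, the sliding clamp of DNA polymerase, fell from 154 ± 2.7 to 81.0 ± 1.9 RPKM (SD, n = 3 per group), MCM4 and MCM3 of the replicative helicase fell by 0.87 and 0.84 on the log2 scale, and E2F7 (0.57), CDK6 (0.39), CDT1 (0.26) and CDK4 (0.15) rose. Of 8 replication-dependent histone genes tested, 7 fell and H2BC5 (0.55) rose, with a median of -0.56 (camera adjusted p = 0.023, and adjusted p = 0.57 with an estimated correlation). H2BC12 (-0.85), H4C8 (-1.05), H2BC21 (-0.97) and H1-2 (-0.53) fell, although near-identical histone copies can share reads. Which forms of histone messenger RNA these libraries captured was not tested, so the fall may not stand for histone messenger RNA as a whole. Of 28 DNA damage and repair genes, 19 fell, 5 rose and 4 did not pass, with a median of -0.21 (camera adjusted p = 0.044, and adjusted p = 0.49 with an estimated correlation). The histone variant H2AX (-1.44), XRCC6 (-0.37), XRCC2 (-0.64) and EXO1 (-0.45) fell, and PALB2 (0.43), BRCA2 (0.22), BARD1 (0.21), XRCC1 (0.16) and CHEK1 (0.08) rose. Without DMSO 1 the adjusted p was 0.051 for the histone list and 0.098 for the repair list. Of 31 G2/M and mitosis genes, 17 rose, 9 fell and 5 did not pass, with a median of 0.14 (camera adjusted p = 0.044, and adjusted p = 0.69 with an estimated correlation). CENPA (0.44), KIF2C (0.53), CENPF (0.40) and PLK1 (0.35) rose, and the list's adjusted p was 0.067 without DMSO 2, 0.066 without DMSO 3 and 0.073 without OTI-611 1.

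The antioxidant, heat shock, interferon and TGF-beta lists fell. Of 23 NRF2 antioxidant genes, 18 fell, 3 rose and 2 did not pass, with a median of -0.44 (camera adjusted p = 4.11e-04, and adjusted p = 0.49 with an estimated correlation). PRDX1 fell from 518 ± 10 to 234 ± 7.7 RPKM (SD, n = 3 per group), PGD of the pentose phosphate pathway fell by 0.53 on the log2 scale and NQO1 by 0.83. The 3 that rose were the glutamate-cysteine ligase subunit GCLC (0.49), TXNRD1 (0.08) and NFE2L2 (0.34), which encodes NRF2 itself. Of 15 heat shock genes, 13 fell, with a median of -0.45 (camera adjusted p = 0.0018, and adjusted p = 0.57 with an estimated correlation). The co-chaperones DNAJA1 (-0.73), BAG3 (-0.79) and AHSA1 (-0.56) and the small heat shock protein gene HSPB1 (-0.81) fell, DNAJB1 (0.61) rose, and HSPA4 stood at 0.02. Of 17 interferon response genes, 14 fell, with a median of -0.46 (camera adjusted p = 0.0052, and adjusted p = 0.57 with an estimated correlation). IFIT3 (-0.90), OAS3 (-1.36) and OASL (-0.67) fell, and ISG15 (0.39) rose. Of 17 TGF-beta and YAP target genes, 12 fell and 3 rose (4 adjusted over the list alone), with a median of -0.31 (camera adjusted p = 0.044, and adjusted p = 0.595 with an estimated correlation). THBS1 (-1.48), TGFBI (-0.82), ID1 (-1.33) and CCN2 (-0.84) fell, SKIL (0.54), CCN1 (0.32) and TGFBR1 (0.13) rose, and the list's adjusted p was 0.078 without DMSO 1.

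**Figure D3:**
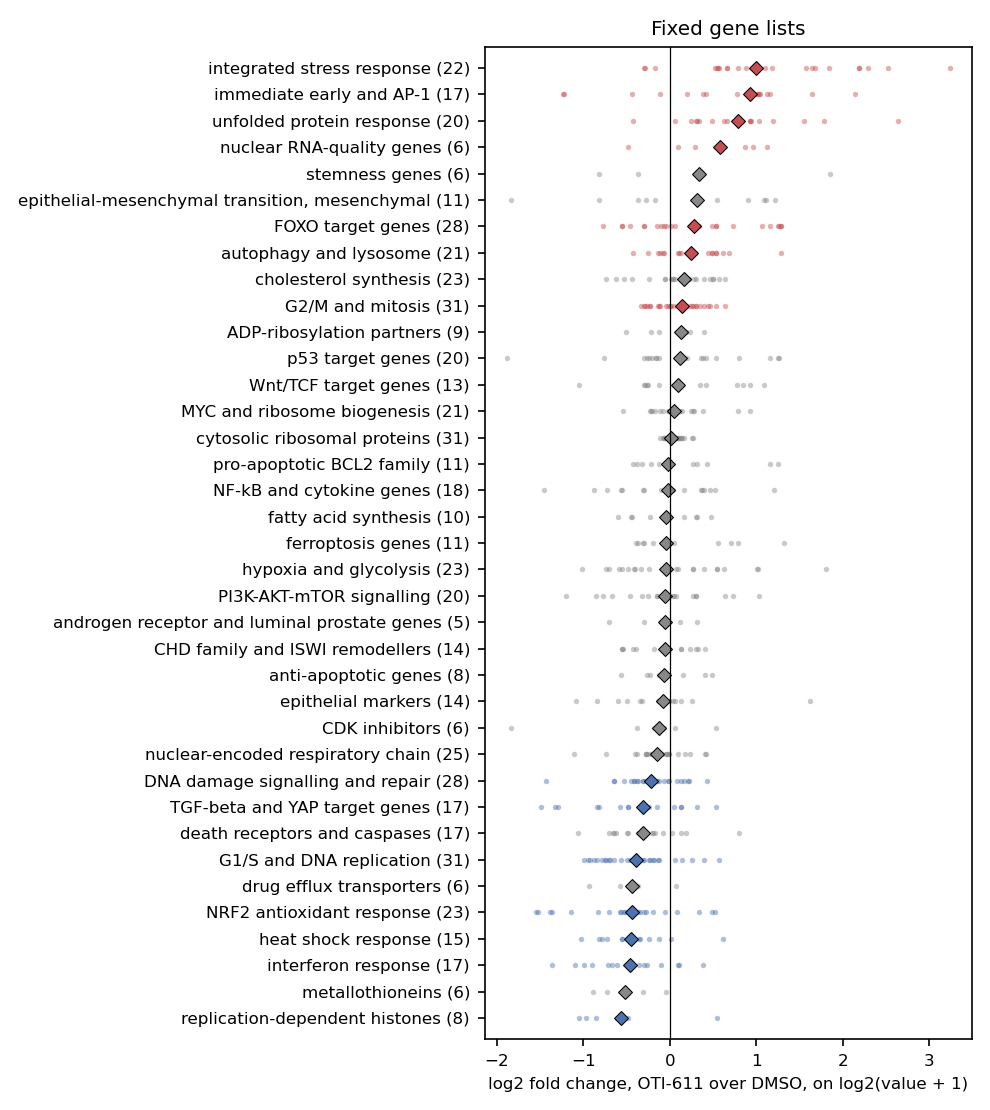
Log2 fold changes (OTI-611 over DMSO, on log2(value + 1)) of the tested members (small points) and their median (diamonds) for the 37 fixed lists with at least 5 tested genes, the number tested in brackets; red lists were higher and blue lists lower at a camera adjusted p under 0.05 with the preset correlation, and grey lists did not pass. The 7 red lists include the integrated stress response at a median of 0.99, and the 7 blue lists include G1/S and DNA replication at -0.40; with an estimated correlation 0 lists passed, the smallest adjusted p being 0.49.

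Among genes of cell death, PMAIP1 (1.16), BBC3 (1.25) and BNIP3L (0.43) rose and BID (-0.38) fell, but the pro-apoptotic BCL2 list did not pass: 5 of 11 rose and 5 fell, the median log2 fold change was -0.02, the mean 0.17 and the test pointed up (camera adjusted p = 0.50). The median turned to 0.11 after quantile normalization and to 0.03 after rescaling to the median log ratio. Of 8 anti-apoptotic genes, 3 rose, including BCL2L1 (0.41) and XIAP (0.48), and 4 fell, including BIRC3 (-0.57) and MCL1 (-0.23; list adjusted p = 0.97). Of 17 death receptor and caspase genes, 2 rose and 11 fell, with a median of -0.31 (camera adjusted p = 0.065). TNFRSF10B, a receptor for the ligand TRAIL, rose by 0.80 on the log2 scale, while TNFRSF1A (-1.06) and CASP6 (-0.70) fell. Of 20 p53 target genes, 10 rose and 7 fell (camera adjusted p = 0.21), with TP53I3 at -1.88 against PMAIP1, TNFRSF10B and GADD45A at 1.16, 0.80 and 1.27. Of 6 CDK inhibitor genes, CDKN1A (0.53) rose and CDKN2C (-1.83), CDKN2B (-0.38) and CDKN2A (-0.18) fell (camera adjusted p = 0.56). The call for CDKN2A was lost without DMSO 2 (limma adjusted p = 0.069), without DMSO 3 (0.060) and without OTI-611 1 (0.056).

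The chromatin and signalling lists went both ways. Among 14 CHD and ISWI remodellers, 6 rose, including CHD2 (0.41) and CHD1 (0.33), and 6 fell, including SMARCA5 (-0.56) and SMARCA1 (-0.54; camera adjusted p = 0.97). Of 9 ADP-ribosylation partners, TNKS2 (0.19), PARG (0.19) and PARP2 (0.40) rose and PARP1 (-0.50) and PARP3 (-0.21) fell (camera adjusted p = 0.59), and adjusted over the list alone 4 rose and 3 fell. Of 13 Wnt/TCF target genes, 6 rose, among them DKK1 (0.85), MYC (0.93), CD44 (0.35) and JUN (0.78), and 5 fell (camera adjusted p = 0.28). Of 11 mesenchymal genes, 6 rose and 3 fell (camera adjusted p = 0.28), with MMP14 (1.22) and TNC (0.55) higher and TGFBI (-0.82) and S100A4 (-1.83) lower. Of 14 epithelial markers, 3 rose and 6 fell (camera adjusted p = 0.67), with CLDN1 (1.62) higher and CDH3 (-0.84), KRT8 (-0.50) and CDH1 (-1.09) lower. Of 20 PI3K-AKT-mTOR genes, 6 rose and 8 fell (camera adjusted p = 0.97), with RICTOR (0.73) and TSC1 (0.64) higher and ERBB2 (-0.86) and RPTOR (-0.66) lower. Of 18 NF-kB and cytokine genes, 6 rose and 7 fell (camera adjusted p = 0.97, pointing up against a mean of -0.08 and a median of -0.02, which turned to 0.03 after rescaling), with TNFAIP3 (1.21) higher and TNFAIP2 (-0.72), CXCL2 (-0.55) and NFKBIA (-0.88) lower. Of 6 stemness genes, KLF4 (1.85), CD44, EZH2 (0.33) and ITGA6 (0.36) rose and ALDH1A3 (-0.82) and BMI1 (-0.36) fell (camera adjusted p = 0.15).

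Metabolic and growth lists did not pass. Of 23 hypoxia and glycolysis genes, 11 rose and 10 fell, with a median of -0.05 and a mean of 0.05 (camera adjusted p = 0.86), and the median turned to 0.06 after quantile normalization and 0.01 after rescaling. HK2, which encodes a hexokinase, rose by 1.81 on the log2 scale, NDRG1 by 1.02 and P4HA1 by 0.63, while the glycolytic enzyme gene ENO1 fell by 0.58. Of 23 cholesterol synthesis genes, 10 rose, such as DHCR7 (0.64) and SREBF2 (0.30), and 5 fell, including IDI1 (-0.62) and PMVK (-0.73; camera adjusted p = 0.11). Of 10 fatty acid synthesis genes, 4 rose, including SCD (0.32), and 5 fell, including ME1 (-0.44), FADS2 (-0.60) and ELOVL6 (-0.45; camera adjusted p = 0.97). Of 25 nuclear genes of the respiratory chain, 10 fell, such as NDUFA1 (-0.74), NDUFB3 (-1.11), COX7C (-0.40) and SDHC (-0.28), and CYC1 (0.18), UQCRC1 (0.09) and NDUFV2 (0.42) rose (camera adjusted p = 0.14). Of 21 MYC and ribosome biogenesis genes, 10 rose, such as MYC, ODC1 (0.79) and WDR43 (0.27), and 6 fell, such as POLR1A (-0.55; camera adjusted p = 0.21). Of 31 cytosolic ribosomal protein genes, 11 rose, with RPL4 (0.27), RPL3 (0.13) and RPS27 (0.14) among them, RPS23 (-0.12) fell and 19 did not pass (camera adjusted p = 0.11). Of 11 ferroptosis genes, TFRC (0.71), SAT1 (1.32), ACSL4 (0.56) and CHAC1 (0.79) rose and 5 fell, HMOX1 (-0.39) among them, with a median of -0.04, turning to 0.02 after rescaling, and a mean of 0.17 (camera adjusted p = 0.67). Of 6 metallothionein genes, whose copies can share reads, MT1E (-0.48), MT1X (-0.89), MT1A (-0.73), MT1M (-0.56) and MT1F (-0.30) fell (camera adjusted p = 0.050). Of 6 drug efflux transporter genes, ABCC2 (-0.58), ABCC5 (-0.45), ABCC3 (-0.43), ABCG2 (-0.93) and ABCC4 (-0.37) fell (camera adjusted p = 0.065).

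Markers of cell identity and RNA quality were read beside these lists. The highest leukocyte marker, CD14, stood at 0.372 RPKM and the highest fibroblast or endothelial marker, ACTA2, at 0.832 RPKM in the mean of DMSO 2 and DMSO 3, against 0.0378 and 0.244 RPKM with OTI-611. Of the hepatocyte and other cell-line markers only NKX2-1, a lung and thyroid transcription factor, was tested, and it fell from 24.4 ± 0.81 RPKM with DMSO (SD, n = 3) by 0.97 on the log2 scale. Of 5 androgen receptor and luminal prostate genes tested, FKBP5 (-0.70) fell, and SLC45A3 (0.31) and PMEPA1 (0.12) did not pass (camera adjusted p = 0.67). SLC45A3 passed without DMSO 1 (limma adjusted p = 0.043) and without DMSO 3 (0.040). The list's other genes with values lay under the minimum for testing. In the mean of DMSO 2 and DMSO 3 the highest of them was STEAP4 at 0.077 RPKM, and KLK3 stood at 0.041 RPKM. The neuroendocrine list had 1 tested gene, the enolase ENO2, which rose by 0.27 on the log2 scale. Of 4 aryl hydrocarbon receptor genes tested, AHR (0.64) and TIPARP (0.34) rose and CYP1B1 (-1.41) and NQO1 (-0.83) fell. Mitochondrially encoded genes were not analysed here. Of 6 nuclear RNA-quality genes, 4 rose and 1 fell, with a median of 0.58 (camera adjusted p = 0.044, and adjusted p = 0.60 with an estimated correlation). GAS5 (0.97), SNHG1 (0.87) and SNHG8 (1.13), host genes of small nucleolar RNAs, and NEAT1 (0.29) rose and TUG1 (-0.48) fell, and the list's adjusted p was 0.051 without DMSO 1 and 0.050 without DMSO 2. Most of the rises were in host genes, so no difference in RNA quality is read from this list.

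Genes at low levels were lower with OTI-611. Against the mean of DMSO 2 and DMSO 3, the summed values of the 3 OTI-611 libraries stood at a ratio of 0.58 for 1292 protein-coding genes with means of 0.05 to 0.2 RPKM, 0.79 for 1764 genes at 1 to 3, 0.91 for 3140 genes at 3 to 10 and 0.98 for 4879 genes at 10 to 100. DMSO 3 over DMSO 2 gave ratios of 0.98 at 0.05 to 0.2 and 1.00 at 10 to 100. Among tested genes, 112 of 268 lincRNA genes fell and 35 rose, and 155 of 366 antisense genes fell and 43 rose. Of 10221 protein-coding genes, 3916 fell and 3047 rose, so the types differed more in their share of rises than of falls. Median log2 fold changes were -0.26 for lincRNA and for antisense genes against -0.05 for protein-coding genes. Antisense values are uncertain where strand was not kept. For the 14 lists that passed, random lists matched on mean expression had median log2 fold changes between -0.06 and -0.02. Each list that rose lay above the 98.3 percentile of its 10000 matched lists, and each that fell at or under the 2.72 percentile. These lists were picked because they passed in camera, and the random lists drew genes independently, so the percentiles are not separate support for them. With an estimated correlation 0 lists passed.

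**Figure D4:**
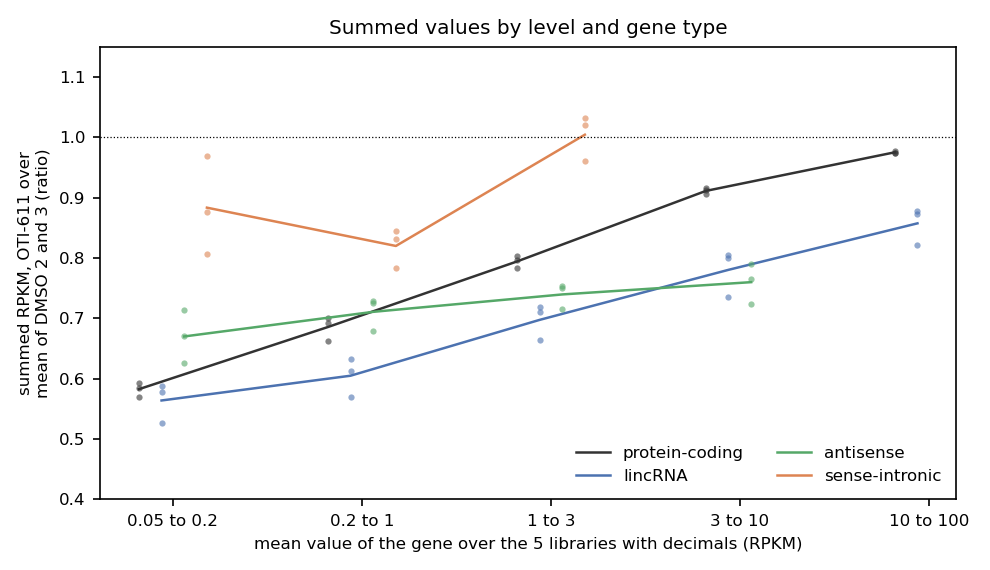
Ratio of summed RPKM, each OTI-611 library over the mean of DMSO 2 and DMSO 3, for genes grouped by their mean RPKM over the 5 libraries with decimals (horizontal axis) and by gene type (colours); points are the 3 OTI-611 libraries, lines their mean, the dotted line a ratio of 1, and the vertical axis starts at 0.4. For protein-coding genes the ratio goes from 0.58 at 0.05 to 0.2 RPKM to 0.98 at 10 to 100.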

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

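The alternatives of 0.5 added to DMSO 1, every library cut to whole numbers and protein-coding genes only were chosen after the data were seen. Over the alternatives that kept the threshold alone, between 5879 and 8655 genes passed against 7805, with none of the shared genes changing direction. Leaving out each library gave 7130 to 8263 genes, 2990 to 3320 higher and 3964 to 5080 lower, 10 to 16 lists, log2 fold changes of 0.96 to 1.04 for FOXO3 and 1.19 to 1.31 for BBC3, and -0.03 to 0.34 for the untested CHD1L. With a log2 fold change of at least 1 required, 479 genes passed, 229 higher and 250 lower, and these counts moved with the settings: 324 higher and 576 lower at a pseudocount of 0.1, 71 and 54 at a pseudocount of 5, 215 and 476 with every library cut to whole numbers, 186 and 307 without DMSO 1, and 260 and 197 after quantile normalization. Of the 37 lists tested, 14 passed, against 0 with an estimated correlation (smallest adjusted p 0.49), 9 with every library cut to whole numbers and 27 with fry, which makes no comparison with other genes. The CHD1L difference was 0.90 at a pseudocount of 0.1, where the 0 in DMSO 1 weighs most, and 0.02 with 0.5 added to DMSO 1. For CHD1L, other scalings and a minimum mean of 5 gave no value. The cause of the other differences was not tested. FOXO3 passed under each alternative that tested it, and so did BBC3, which a minimum mean of 5 left out. Among lists that did not pass, the median log2 fold change also turned from -0.05 to 0.05 for PI3K-AKT-mTOR and from -0.06 to 0.05 for androgen receptor and luminal genes after quantile normalization, from -0.04 to 0.02 for fatty acid synthesis after rescaling, and from 0.10 to -0.07 for Wnt/TCF targets without DMSO 1. Of 171 named genes past the threshold, 167 kept their side and direction in each alternative that tested them, and 4 (CDKN2A, RPL3, RPS23 and RPS27) lost the call in at least 1. FOXO4, SLC45A3 and PMEPA1 gained one. Centring moved the share of higher calls from 42.7% to 50.1%. The replicate block changed the count of genes to 7756. Deviations of same-numbered libraries correlated at 0.12, 0.10 and -0.0053, and those of differently numbered libraries at -0.19 to 0.11, highest for DMSO 2 with OTI-611 3. With 3 libraries per group these values cannot tell whether the numbers pair the samples, which the labels do not state. The alternatives set for counts were not run, since the table used holds none. In simulated data with 200 genes changed, small changes were the most often missed, with 38.8% recovered at 0.25 on the log2 scale. That share does not carry over to the data, where far more genes passed.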

Other observations

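The gene families in this part were chosen after their values were seen, and so were the tests of low-level genes, of CHD1L and ribosomal protein genes and of FOXO targets. Of 25 families looked at, 24 had at least 5 tested genes, and 8 of these passed in camera with p adjusted over the 24, against 0 with an estimated correlation. The adjustment does not cover the choice of families by their values, so their p-values are not independent support. Genes that charge transfer RNA in the cytosol rose: of 19 cytosolic aminoacyl-tRNA synthetase genes tested, 14 were higher and 5 lower with OTI-611, with a median log2 fold change of 0.56 (camera adjusted p = 6.45e-04, and adjusted p = 0.52 with an estimated correlation). AARS1, SARS1 and GARS1 rose by 1.45, 1.06 and 1.13 on the log2 scale, while RARS1 (-0.47), HARS1 (-0.45), KARS1 (-0.30), FARSB (-0.24) and QARS1 (-0.16) fell. Of 15 mitochondrial synthetase genes, 3 rose and 7 fell, with a median of -0.07 (camera adjusted p = 0.58). Whether the cytosolic and mitochondrial families differ was not tested. Of 336 numbered zinc finger genes, 127 rose and 43 fell, with a median of 0.13 (camera adjusted p = 8.20e-04, and adjusted p = 0.80 with an estimated correlation).

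The tubulin, SR splicing factor, proteasome, redox enzyme, aldo-keto reductase and CCT chaperonin families fell. Of 11 tubulin genes, a family narrowed after its values were seen to leave out genes that encode no tubulin, 9 fell and 2 did not pass, with a median of -0.59 (camera adjusted p = 6.45e-04, and adjusted p = 0.52 with an estimated correlation). TUBA1A (-1.70) and TUBB4A (-1.01) fell furthest, although tubulin copies can share reads. Of 11 SR splicing factor genes, 10 fell, SRSF3 (-1.48) and SRSF1 (-1.35) furthest, and SRSF4 (0.35) rose (camera adjusted p = 8.20e-04, and adjusted p = 0.52 with an estimated correlation). Of 37 proteasome subunit genes, 29 fell, PSMA3 (-0.69) among them, and PSMD2 (0.21) rose (camera adjusted p = 2.21e-04, and adjusted p = 0.52 with an estimated correlation). Of 33 peroxiredoxin, thioredoxin and glutathione enzyme genes, some of which are also in the NRF2 list, 24 fell and 3 rose, with GPX8 (-0.99) and GSTP1 (-0.71) lower (camera adjusted p = 6.45e-04, and adjusted p = 0.52 with an estimated correlation). Of 8 aldo-keto reductase genes, whose copies can share reads, 6 fell, AKR1C2 (-1.55) and AKR1B10 (-1.53) furthest (camera adjusted p = 0.0070, and adjusted p = 0.64 with an estimated correlation). Of 6 CCT chaperonin genes, CCT3 (-0.39), CCT5 (-0.31), CCT2 (-0.29), CCT6A (-0.17) and CCT7 (-0.08) fell (camera adjusted p = 0.047, and adjusted p = 0.68 with an estimated correlation), and the family's adjusted p was 0.11 without DMSO 1. Of 24 host genes of small nucleolar RNAs, 10 rose and 10 fell (camera adjusted p = 0.26), with SNHG17 at 0.86 and SNHG10 at -1.07.

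The 6 libraries can be split into 3 and 3 in 10 ways, and the real split, with 7805 genes, is 1 of the 10, the highest of the others calling 1 gene. With 10 splits the share cannot go under 0.1, too few for a test at 0.05.

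Low-level genes were lower with OTI-611, whose libraries had the higher estimated depth (37.2 M to 37.6 M reads against 30.7 M and 32.3 M, a comparison looked at first), and the fall eased as the level rose. A single scale factor per library would move all levels alike, whereas the median log2 ratio of protein-coding genes at 0.05 to 1 RPKM lay -0.59 from that at 10 to 100 (95% bootstrap interval -0.64 to -0.55). Less genomic DNA spread evenly over genes, as the only cause, would take the same RPKM from each gene. Genes at 1 to 3, however, lost 0.39 RPKM more per gene than genes at 0.05 to 0.2 (interval 0.34 to 0.43). The mean loss at 1 to 3 was 0.45 RPKM, more than genes at 0.05 to 0.2 held on average. That less genomic DNA made up a share of the 0.061 RPKM lost at 0.05 to 0.2 therefore stays open. Less unspliced RNA, as the only cause, would lower sense-intronic genes as far as protein-coding genes of their level. At 0.05 to 1 the sense-intronic ratio, however, lay 0.16 higher (interval 0.079 to 0.25), at 0.83 against 0.67. Sense-intronic genes were lower too, so less unspliced RNA as part of the cause stays open. Other differences in library making between the groups and a treatment effect on weakly transcribed genes stay open and were not tested, and bootstrapping genes does not cover the spread between libraries.

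CHD1L, at 0.655 RPKM over the 5 libraries with decimals, is low for the gene the series title targets, and some genes that growing cells need were low too: 11 of 77 ribosomal protein genes lay under 20 RPKM against a median of 292, RPS25 at 0.0665 and RPS3A at 0.29. If reads on exons shared with another gene were not counted, a candidate explanation, such genes would share more exon bases, and the 11 had a mean of 16.1% of their exon bases shared with other genes in GENCODE v29 against 5.63% in the others (permutation p = 0.0027, two-sided, 100000 permutations), although RPL10, with the largest share of the 77 at 55.5%, stood at 375 RPKM. Over all protein-coding genes the median was 4.36 RPKM at a share of 0 to 10%, 4.74 at 10 to 25%, 2.16 at 25 to 50%, 0.272 at 50 to 75% and 0.0394 at 75 to 100%. That share is 7.85% for CHD1L, in the band with a median of 4.36 RPKM, and 2.00% for the ribosomal protein gene RPS18, at 1.03 RPKM, so sharing in this annotation would remove only a small part of their reads, and the authors' own annotation was not used here. Low CHD1L expression in these cells also stays open, and other causes of the low values were not tested. No value used here decides between them.

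FOXO3 rose and the FOXO target list passed upward with the preset correlation but not with an estimated one (adjusted p = 0.57 with an estimated correlation). The whole numbers of DMSO 1 do not account for the call at the preset correlation, since without that library its adjusted p was 0.032. Another explanation is that members shared with other fixed lists, such as PMAIP1, GADD45A and MAP1LC3B, carry the list. The 13 tested members in no other list had a median log2 fold change of 0.01 with 6 higher and 5 lower (camera p = 0.54), against a median of 0.32 in the 15 shared members (camera p = 0.0014, and p = 0.15 with an estimated correlation). The difference between these parts was not tested, so a response of FOXO targets and one of stress genes that FOXO lists also hold cannot be told apart for this list.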
